A study of Mus musculus with 21 samples.

How the data were processed

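RNA was measured by sequencing in 21 mouse libraries. Total RNA was extracted with TRIzol and libraries followed standard Illumina protocols, per the labels' protocols; whether polyadenylated RNA was selected or rRNA removed, and whether strand was kept, is not given in the sources used here. HISAT2 2.2.1, featureCounts 1.5.0-p3 and the genome build mm10 are named in the submitters' processing notes, with no order of steps. Groups came from the labels' genotype and treatment fields and replicate numbers from the sample titles. Nothing in the labels says that replicates came from separate mice or cultures, so p-values measure only the spread between these libraries. Labels and design text give LPS for 6 h, nigericin for 30 min and MCC950 for 2 h before, and the design text alone gives the doses (1 µg/mL, 10 µM and 10 µM). The labels give 6 weeks for oil and CCl4 where the design text gives 8 weeks for CCl4, and both give 8 weeks for TAA.

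The authors deposited 3 tables, normalized separately, and tests were made only within a table. The TAA table holds raw counts and FPKM, per the file headers, for 34280 genes. The CCl4 table and the hepatocyte table hold FPKM only, with gene lengths, as deposited by the authors, for 54532 genes. In these 2 tables FPKM times gene length was a whole multiple of 1 step per library for 100% of values above 0 (within 0.05 of a whole number), which gave the reads per gene. FPKM times length summed to 1096240 to 1344060 per oil library and 857315 to 916803 per wild-type CCl4 library. In the libraries labelled Sting knockout it summed to 822718 to 1215060. These sums differed between oil and wild-type CCl4, and the main fits applied no rescaling. The authors' scaling was thus not to the sum over genes. How it was made is not given in the sources used here. Some mitochondrial genes and their nuclear copies hold nearly equal high counts in the TAA table, as reads counted at several places would give, which was not tested.

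CCl4, Sting and MCC950 comparisons used limma 3.58.1 on log2(FPKM + 1) with an intensity trend, over genes with a mean of at least 1 FPKM; the 3 groups of the CCl4 table shared 1 fit. Fold changes there are on the log2(FPKM + 1) scale, which understates the change of low genes. The Nlrp3 comparison used edgeR 4.0.16 (quasi-likelihood test, TMM factors, filterByExpr) on counts as deposited. Tests were two-sided with Benjamini-Hochberg adjustment, and a gene was called at an adjusted p under 0.05. Values are means ± SD of deposited FPKM over 3 libraries. Sting1 and Nlrp3 were also compared by an exact permutation test. R was version 4.3.3 and DESeq2, an alternative, 1.42.0.

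The test, samples, alternatives, 42 gene lists and rule for named genes were fixed before the data were examined. Lists were tested with camera (preset correlation 0.01, and again with an estimated correlation) and fry, where at least 4 members were tested; set p-values were adjusted over the 28 lists tested in hepatocytes or the 40 tested in each liver comparison. Of 804 list genes, 799 matched 1 gene in the TAA table and 801 in the others. The rule names Sting1, Nlrp3 and 6 inflammasome genes with their values; the 8 called coding genes with the largest rise and fall at a mean of at least 1 FPKM and no overlap of groups, or the 5 with the smallest p each way where none was called; and up to 3 leading members of each list past camera. Genes outside this rule are named as chosen after their values were seen.

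The tests were run on simulated data with 200 changed genes. Of genes changed 2-fold and 4-fold, 92% and 95% were recovered with the spread of the MCC950 comparison, 7% and 60% with that of CCl4, 2% and 60% with that of Sting and 2% and 47% with that of Nlrp3, with 12, 5, 5 and 6 calls on unchanged genes and 0 with the wrong sign. Replicate numbers pair libraries by the rule used here where same-numbered libraries deviate together with a correlation over 0.1 for every pair. This held for CCl4 against oil (0.22, 0.32 and 0.52) and for the Sting comparison (0.19, 0.18 and 0.12), from the data alone, since the labels name no shared litter or day. With the replicate number as a block CCl4 gave 1182 higher and 1045 lower, and the Sting comparison 0 and 0.

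Alternatives were the pseudocount, the filter, the scaling, the trend, robust moderation, array weights, coding genes alone, the block, each library left out and, for counts, RLE factors, DESeq2 and limma. Chosen after seeing the data were edgeR on recovered reads, the Nlrp3 fit without mitochondrial, rRNA and pseudogene counts, thresholds of 0.04 and 0.06, and the CCl4 fit without replicate 2 of the libraries labelled Sting knockout. Coordinates are those of the deposited tables on mm10.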

Results

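The series holds 21 mouse RNA-seq libraries in 7 groups of 3. By the study's title it addresses whether the DNA-sensing adaptor STING acts on hepatocyte pyroptosis in fibrotic liver through the NLRP3 inflammasome. There were 6 libraries of primary hepatocytes given lipopolysaccharide (LPS) and nigericin, an ionophore that activates NLRP3, and 3 of these had first received the NLRP3 inhibitor MCC950. Another 9 libraries came from liver after oil or the hepatotoxin carbon tetrachloride (CCl4), the latter in wild-type mice and in mice labelled Sting knockout. The last 6 came from liver after thioacetamide (TAA), a hepatotoxin that also gives fibrosis, in wild-type mice and in mice with Nlrp3 deleted in hepatocytes. Total counts per TAA library were 32096879 to 68913793. Reads recovered from the deposited values were 14353483 to 16684832 per library of the CCl4 table and 14883710 to 17157586 per hepatocyte library. Unstimulated hepatocytes, livers without TAA and oil-treated Sting knockout livers were not analysed here.

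The targeted genes were examined first. Sting1 (ENSMUSG00000024349, chromosome 18, 35733678 to 35740554, mm10), which encodes STING, was at 6.10, 5.15 and 4.74 FPKM in the wild-type CCl4 livers. In the livers labelled Sting knockout it was at 3.42, 1.98 and 5.28 FPKM. The difference of means was −1.77 FPKM (exact two-sided permutation p = 0.3, where 3 against 3 libraries cannot give less than 0.1). The highest of these values lies inside the wild-type range. The sample titles name these 3 libraries knockouts but carry codes that begin with SWT, whose meaning is not given in the sources used here. For both reasons the group is called the libraries labelled Sting knockout throughout. The labels do not describe the allele, and an allele that leaves the RNA in place would not lower these values. Nlrp3 (ENSMUSG00000032691, chromosome 11, 59541568 to 59566956) had 36, 24 and 28 counts in the wild-type TAA livers and 23, 105 and 83 counts in the livers with the hepatocyte deletion. Its FPKM was 0.143 ± 0.031 and 0.233 ± 0.146 (SD, n = 3 each), a difference in the direction opposite to a loss (exact two-sided permutation p = 0.4). Whole liver holds Nlrp3 RNA of other cells, so these values neither show nor exclude the loss in hepatocytes. In the hepatocyte libraries Nlrp3 had 0 to 4 recovered reads.

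**Figure D1:**
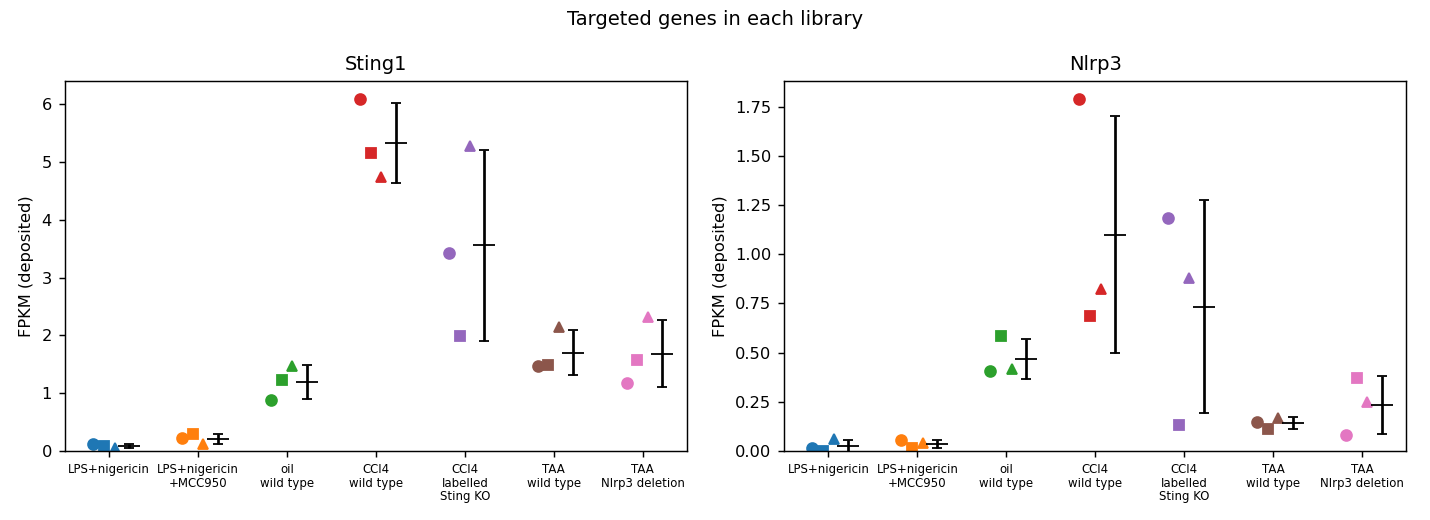
FPKM of Sting1 (left) and Nlrp3 (right) as deposited, 1 point per library in 7 groups of 3, with the group mean and SD as a black dash and bar beside the points (the 3 tables were normalized separately). Sting1 in the libraries labelled Sting knockout spans 1.98 to 5.28 FPKM, against 4.74 to 6.10 FPKM in the wild-type CCl4 libraries.

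In hepatocytes given LPS and nigericin, MCC950 was set against no inhibitor, which asks what blocking NLRP3 changes. Gsdmd, which encodes the pore-forming protein of pyroptosis, was at 17.0 ± 0.81 FPKM without and 14.5 ± 1.59 FPKM with MCC950 (SD, n = 3 each), a difference that did not pass (limma adjusted p = 0.407). Il18, a cytokine processed by the inflammasome, was at 1.59 ± 0.107 and 1.71 ± 0.25 FPKM (limma adjusted p = 0.777). Nlrp3, Sting1, Pycard, Casp1, Casp4 and Il1b lay below a mean of 1 FPKM and did not enter the limma test. Sting1 was at 0.0833 ± 0.0323 FPKM without and 0.212 ± 0.0855 FPKM with MCC950, from 4, 3 and 2 and from 9, 12 and 5 recovered reads, with no overlap (exact two-sided permutation p = 0.1, the smallest possible). Nlrp3 had an exact two-sided permutation p of 0.8. The hepatocyte identity list fell as a set (24 genes, median log2 fold change −0.13, camera adjusted p = 6.61e-05, and adjusted p = 0.351 with an estimated correlation). None of its members passed the gene test, and 4 were lower when adjusted over the list alone. Among its leading members were Hpd, of tyrosine breakdown (144 ± 4.9 and 120.0 ± 6.1 FPKM), and Tat (32.9 ± 0.77 and 28.6 ± 1.28 FPKM).

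With MCC950 the periportal list fell as a set too (16 genes, median −0.13, camera adjusted p = 0.0465, and adjusted p = 0.846 with an estimated correlation). None of its members passed and 1 did adjusted over the list alone. Asl, of the urea cycle, was at 60.4 ± 2.45 and 49.1 ± 2.05 FPKM. The mitochondrially encoded list rose as a set (12 genes, median 0.20, adjusted p = 0.0465, and adjusted p = 0.846 with an estimated correlation), with 0 members past the gene test and 0 adjusted over the list alone. Its member mt-Nd4 was at 1679 ± 306 and 2015 ± 169 FPKM. Both calls ended with TMM-like scaling (adjusted p = 0.0517 and 0.0713) and with single libraries left out. Without MCC950 replicate 1, 2 or 3 the mitochondrial set had an adjusted p of 0.488, 0.094 and 0.224, and without replicate 2 or 3 given no inhibitor of 0.463 and 0.275. Without MCC950 replicate 1 or 2 the periportal set had 0.121 and 0.094, and without replicate 2 given no inhibitor it had 0.238. The inflammasome list (6 genes, median 0.06, mean −0.01), the interferon-stimulated list (15 genes, median −0.07) and the list of NF-kB cytokines and chemokines (15 genes, median 0.01) did not pass (adjusted p = 0.876, 0.639 and 0.639).

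Of 9835 genes tested between MCC950 and no inhibitor, limma called 0 higher and 0 lower. An unadjusted p under 0.05 was found for 1168, where 491.75 would be expected by chance for these genes. Of 12050 genes tested, edgeR on recovered reads called 0, with 1535 under an unadjusted p of 0.05, for which the chance value above does not hold. The limma count was 649 and 616 without MCC950 replicate 1 or 3, and 1781 and 711 without replicate 1 or 2 given no inhibitor. The groups did not overlap at 19.7% of genes, against 10% by chance. The smallest limma adjusted p of any gene was 0.301. Of coding genes whose groups did not overlap, those with the smallest p did not pass (limma adjusted p = 0.39 each). Among them Twistnb, Xkr9, Trp53inp1, Acot2 and Eid1 were higher with MCC950, and Atf6b, Ubac2, Mvb12a, Tmem203 and Ddt lower. The p53-induced Trp53inp1 was at 13.5 ± 0.52 FPKM without and 16.6 ± 0.57 FPKM with MCC950. Tmem203 was at 6.27 ± 0.74 and 3.82 ± 0.36 FPKM.

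CCl4 was set against oil in wild-type liver, which asks what the fibrosis model itself changes. Genes of scar matrix and myofibroblasts rose: Col1a1, of type I collagen (chromosome 11, 94936224 to 94953042), went from 1.10 ± 0.38 to 67.4 ± 42.3 FPKM (SD, n = 3), 29.2-fold on the log2(FPKM + 1) scale (limma adjusted p = 0.000161). Col3a1 went from 3.62 ± 0.85 to 69.5 ± 22.4 FPKM and Acta2, smooth muscle actin, from 1.33 ± 0.53 to 51.2 ± 39.2 FPKM. Macrophage genes rose with them, led by Gpnmb (chromosome 6, 49036546 to 49070929) from 0.0516 ± 0.0054 to 28.2 ± 2.04 FPKM (limma adjusted p = 4.68e-06). Pericentral hepatocyte genes fell, among them Glul, glutamine synthetase (266 ± 21.7 to 23.8 ± 7.22 FPKM), and Cyp2e1, the enzyme that activates CCl4 (3236 ± 847 to 210.0 ± 172 FPKM). The steepest falls were in major urinary protein genes, with Mup17 (chromosome 4, 61591929 to 61595871) from 1970 ± 1142 to 0.247 ± 0.229 FPKM. These genes are near-identical copies that share reads, so the value of any single copy is uncertain.

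In the list of fibrillar and basement matrix 23 of 26 tested genes rose under CCl4 and 1 fell (24 and 1 adjusted over the list alone), with a camera adjusted p of 9.98e-18 (adjusted p = 0.13 with an estimated correlation). Matrix remodelling and TGF-beta genes rose in 18 of 24 (20 adjusted over the list alone, adjusted p = 8.86e-14, and adjusted p = 0.153 with an estimated correlation). Among them the collagenase Mmp13 went from 0.0717 ± 0.0457 to 3.02 ± 0.46 FPKM. Of 17 stellate cell and myofibroblast genes 7 rose and 1 fell (8 and 2 adjusted over the list alone, adjusted p = 0.00137, and adjusted p = 0.153 with an estimated correlation). Pdgfra, a growth factor receptor of these cells, went from 0.912 ± 0.133 to 3.38 ± 0.32 FPKM. Cell cycle genes rose in 30 of 31 (31 adjusted over the list alone, adjusted p = 6.6e-33, and adjusted p = 0.0779 with an estimated correlation). Ube2c, which acts at the end of mitosis, went from 0.147 ± 0.164 to 14.7 ± 3.48 FPKM. Other steep rises were in Lcn2, an iron-carrier-binding protein (7.53 ± 7.25 to 192 ± 153 FPKM), and Ly6d (1.68 ± 0.51 to 56.5 ± 12.8 FPKM). Sprr1a was listed at 0 in each oil library and had a mean of 31.4 ± 27.6 FPKM under CCl4.

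Of the immune lists, that of recruited macrophages and monocytes rose in 20 of 20 genes (20 adjusted over the list alone, camera adjusted p = 4.49e-22). It was the 1 list of 32 past camera that kept its call with an estimated correlation (adjusted p = 0.00267 with an estimated correlation). Lgals3, galectin-3, went from 3.44 ± 0.99 to 59.9 ± 34.7 FPKM. Kupffer cell genes rose in 7 of 17 (9 adjusted over the list alone, adjusted p = 0.000248, and adjusted p = 0.341 with an estimated correlation). Neutrophil genes rose in 6 of 8 (8 adjusted over the list alone, adjusted p = 2.79e-06, and adjusted p = 0.13 with an estimated correlation), with S100a9 from 5.27 ± 3.58 to 39.5 ± 16.5 FPKM. MHC class II genes rose in 5 of 7 (6 adjusted over the list alone, adjusted p = 0.000185, and adjusted p = 0.336 with an estimated correlation). NF-kB cytokines and chemokines rose in 11 of 22 (14 adjusted over the list alone, adjusted p = 3.26e-09, and adjusted p = 0.154 with an estimated correlation), with Ccl7 from 0.319 ± 0.137 to 5.17 ± 0.81 FPKM.

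B and plasma cell genes passed under CCl4 as a set, with 1 of 8 members past the gene test (6 adjusted over the list alone, camera adjusted p = 0.000467, and adjusted p = 0.224 with an estimated correlation). That member was Cd79b, whose call ended without CCl4 replicate 1 or 2 or oil replicate 1 or 3 (limma adjusted p = 0.0766, 0.05, 0.105 and 0.0784). T and NK cell genes passed as a set with 0 of 7 past the gene test and 0 adjusted over the list alone (adjusted p = 0.0205, and adjusted p = 0.439 with an estimated correlation), and without CCl4 replicate 1 the set did not pass (0.229). Cholangiocyte genes likewise had 0 of 9, and 0 adjusted over the list alone (adjusted p = 0.0302, and adjusted p = 0.361 with an estimated correlation), and without CCl4 replicate 3 the set did not pass (0.189). Both sets also failed under quantile normalization (0.0996 and 0.157), T and NK cells with coding genes alone (0.056), and cholangiocytes with edgeR on recovered reads or no filter (0.0775 and 0.0779). Sinusoidal endothelium did not pass (18 genes, median −0.16, adjusted p = 0.899).

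Genes of the sensing pathways named by the study also rose under CCl4. Sting1 went from 1.19 ± 0.29 to 5.33 ± 0.69 FPKM (SD, n = 3, limma adjusted p = 0.00335) and Casp1 from 2.62 ± 0.67 to 9.0 ± 2.28 FPKM (0.00354). Pycard, the inflammasome adaptor, went from 0.338 ± 0.183 to 1.76 ± 0.25 FPKM (0.00563, and 0.057 under quantile normalization). Casp4 went from 0.531 ± 0.111 to 2.02 ± 0.74 FPKM (0.027), a call that ended without CCl4 replicate 1 or 3 (0.0881 and 0.0728) or oil replicate 1, 2 or 3 (0.0936, 0.0901 and 0.0664). Gsdmd (14.7 ± 2.58 and 16.3 ± 5.9 FPKM), Il1b (1.93 ± 0.74 and 4.32 ± 2.08 FPKM) and Il18 (11.5 ± 3.84 and 13.2 ± 4.33 FPKM) did not pass (limma adjusted p = 0.901, 0.103 and 0.83). Nlrp3 was at 0.468 ± 0.101 and 1.10 ± 0.603 FPKM, below the level tested (exact two-sided permutation p = 0.1, the smallest possible).

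The inflammasome list rose in 6 of 13 genes under CCl4 (7 adjusted over the list alone, camera adjusted p = 0.000961, and adjusted p = 0.336 with an estimated correlation). The cGAS-STING list rose in 4 of 10 and fell in 1 (6 and 1 adjusted over the list alone, adjusted p = 0.019, and adjusted p = 0.368 with an estimated correlation). At a mean of at least 5 FPKM neither set passed (0.119 and 0.0892). Interferon-stimulated genes rose in 4 of 34 (2 adjusted over the list alone, adjusted p = 3.17e-07, and adjusted p = 0.398 with an estimated correlation), among them Ifi27l2a (12.3 ± 5.04 to 56.6 ± 27.1 FPKM). The p53 targets rose in 3 of 16 (5 adjusted over the list alone, adjusted p = 0.00299, and adjusted p = 0.262 with an estimated correlation), with Cdkn1a from 3.19 ± 0.94 to 18.8 ± 9.82 FPKM. In the unfolded protein and integrated stress response 5 of 22 genes rose and 1 fell (5 and 1 adjusted over the list alone, adjusted p = 0.00368, and adjusted p = 0.398 with an estimated correlation). Atf3 went from 0.615 ± 0.178 to 11.8 ± 1.15 FPKM, and without CCl4 replicate 2 this set did not pass (0.0811). Immediate early genes rose in 4 of 15 (6 adjusted over the list alone, adjusted p = 0.00193, and adjusted p = 0.341 with an estimated correlation).

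Acute phase proteins rose in 4 of 24 under CCl4 (4 adjusted over the list alone, camera adjusted p = 0.0105, and adjusted p = 0.438 with an estimated correlation), a set that did not pass without oil replicate 1 (0.0772), with edgeR on recovered reads (0.0978) or with no filter (0.088). NRF2 targets did not pass (adjusted p = 0.24), and their median (−0.11) and mean (0.35) differ in sign. Heat shock genes, ribosomal proteins, histone methyltransferase complexes, red blood cell genes, and mesothelium and muscle genes did not pass either (adjusted p = 0.268, 0.444, 0.702, 0.663 and 0.165).

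Hepatocyte lists fell under CCl4. Of 16 pericentral genes 10 fell (11 adjusted over the list alone, camera adjusted p = 3.43e-08, and adjusted p = 0.154 with an estimated correlation), with Oat from 427 ± 104 to 25.3 ± 6.01 FPKM. Bile acid genes fell in 13 of 18 and rose in 1 (14 and 1 adjusted over the list alone, adjusted p = 1.23e-06, and adjusted p = 0.153 with an estimated correlation). Cyp8b1, the sterol 12-alpha-hydroxylase, went from 194 ± 36.4 to 14.7 ± 9.51 FPKM. Drug-metabolising enzymes fell in 12 of 28 (16 fell and 1 rose adjusted over the list alone, adjusted p = 7.86e-06, and adjusted p = 0.341 with an estimated correlation). Fatty acid oxidation genes fell in 10 of 25 (15 fell and 1 rose adjusted over the list alone, adjusted p = 2.01e-06, and adjusted p = 0.262 with an estimated correlation), with Acsl1 from 116 ± 14.7 to 35.9 ± 6.2 FPKM. Lipogenesis genes fell in 5 of 19 (8 adjusted over the list alone, adjusted p = 0.000185, and adjusted p = 0.341 with an estimated correlation). Clock genes fell in 3 of 14 and rose in 1 (3 and 1 adjusted over the list alone, adjusted p = 0.0157, and adjusted p = 0.341 with an estimated correlation). The clock set did not pass with edgeR on recovered reads (0.0662) or at a mean of at least 5 FPKM (0.0626).

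Periportal genes fell in 6 of 18 under CCl4 and rose in 1 (7 and 1 adjusted over the list alone, camera adjusted p = 0.00589, and adjusted p = 0.418 with an estimated correlation), with Hal, of histidine breakdown, from 129 ± 1.91 to 44.3 ± 4.48 FPKM. Hepatocyte identity genes fell in 5 of 24 (6 adjusted over the list alone, adjusted p = 0.000416, and adjusted p = 0.368 with an estimated correlation). Mitochondrially encoded genes fell in 2 of 13, mt-Cytb and mt-Nd4 (6 adjusted over the list alone, adjusted p = 0.000392, and adjusted p = 0.341 with an estimated correlation). Without any 1 of CCl4 replicates 1, 2 and 3 or oil replicates 2 and 3 these 2 genes were not called (limma adjusted p from 0.0603 to 0.126). Nuclear oxidative phosphorylation fell as a set with 0 of 32 past the gene test, and 0 adjusted over the list alone (adjusted p = 5.61e-05, and adjusted p = 0.439 with an estimated correlation). Cholesterol synthesis fell with 0 of 22, and 0 adjusted over the list alone (adjusted p = 0.0209, and adjusted p = 0.438 with an estimated correlation), and without CCl4 replicate 1 or oil replicate 1 it did not pass (0.178 and 0.136). These 5 sets did not pass under quantile normalization, where the hepatocyte identity median was −0.06 in place of −0.71. Periportal and cholesterol synthesis genes did not pass at a mean of at least 5 FPKM either (0.0622 and 0.151).

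Sex-biased hepatic genes moved in both directions under CCl4. Of 14 male-biased genes 13 fell (13 adjusted over the list alone, camera adjusted p = 1.86e-10, and adjusted p = 0.239 with an estimated correlation), with Cyp4a12a from 149 ± 45.7 to 6.46 ± 8.8 FPKM and Hsd3b5 from 249 ± 40.8 to 11.1 ± 18.9 FPKM. Of 5 female-biased genes 2 rose (5 adjusted over the list alone, adjusted p = 0.00193, and adjusted p = 0.336 with an estimated correlation), with Cyp17a1 from 1.36 ± 0.22 to 10.1 ± 5 FPKM. CCl4 replicate 3 held Xist at 79.9 FPKM and the Y-linked Ddx3y at 0.0414 FPKM. In the other wild-type CCl4 and the oil libraries Xist was at most 0.0128 FPKM and Ddx3y at least 11.5 FPKM. Without that library the male-biased median was −2.63 in place of −3.08 and the female-biased median 1.63 in place of 2.12, and both sets passed camera. The call of the female-biased Atp6v0d2 ended without it (limma adjusted p = 0.0653), and also without oil replicate 1 or 2 (0.121 and 0.104).

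Of 11511 genes tested, limma called 1058 higher and 708 lower under CCl4, of which 844 and 509 differed by at least 2-fold. The groups did not overlap at 38.1% of genes, against 10% by chance. Without CCl4 replicate 3, the library with Xist, 941 were higher and 463 lower, and without CCl4 replicate 2, 431 were lower. Without oil replicate 1, 2 or 3, 675, 674 and 678 were higher and 299, 262 and 290 lower. At a mean of at least 5 FPKM 363 genes were higher and 514 lower, and array weights gave 1813 and 1967.

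**Figure D2:**
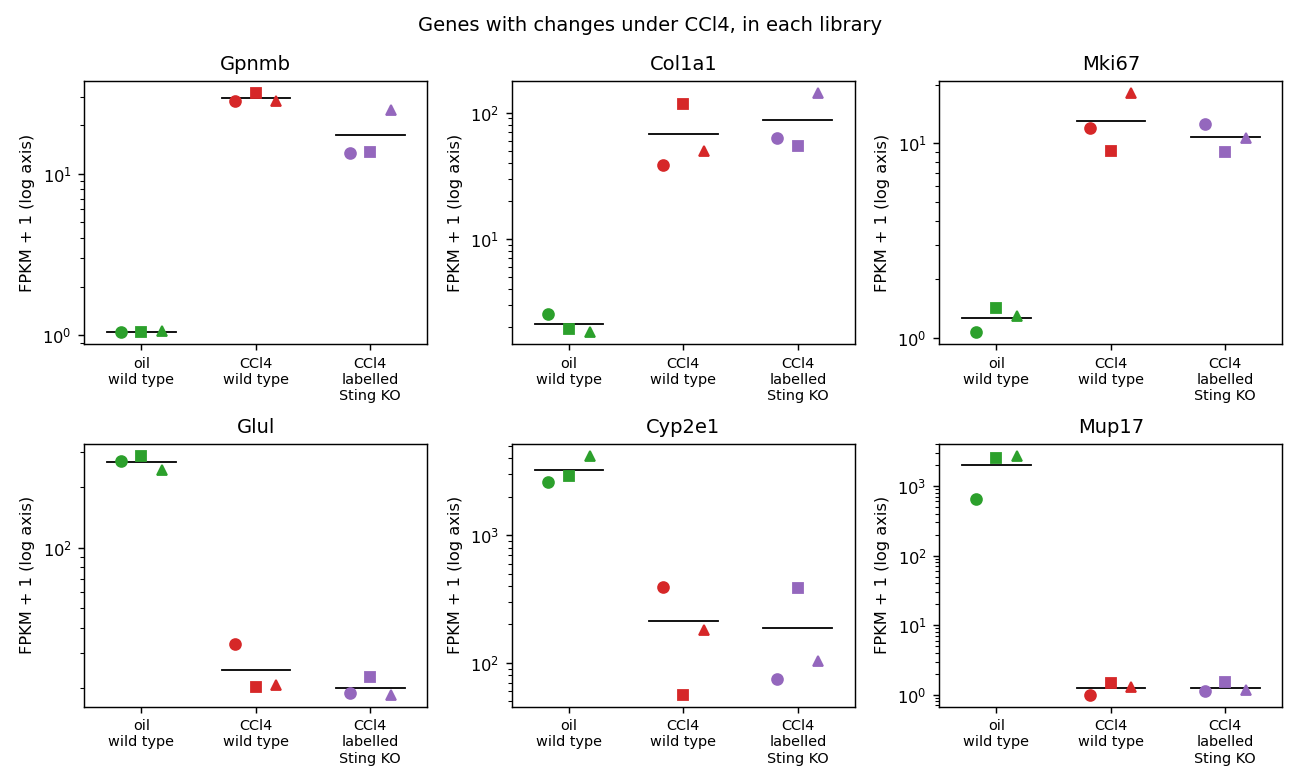
FPKM + 1 on a log axis for 6 genes in the oil, CCl4 and CCl4 labelled Sting knockout livers, 1 point per library (3 per group), with a line at the group mean. Gpnmb, Col1a1 and Mki67 are higher, and Glul, Cyp2e1 and Mup17 lower, in both CCl4 groups than in oil.

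The libraries labelled Sting knockout were set against wild type, both under CCl4, which asks what loss of STING changes in the fibrosis model. Hemoglobin genes were higher in the livers labelled knockout, but none passed. Hbb-bs was at 318 ± 211 FPKM in wild type and 1365 ± 353 FPKM in the labelled group (SD, n = 3 each) and Hbb-bt at 39.0 ± 31.6 and 139 ± 5.44 FPKM (limma adjusted p = 0.761 each). Inflammasome genes did not pass either: Casp1 was at 9.0 ± 2.28 and 5.93 ± 1.48 FPKM and Gsdmd at 16.3 ± 5.9 and 18.3 ± 6.73 FPKM (limma adjusted p = 0.761 and 0.866). Col1a1 was at 67.4 ± 42.3 FPKM in wild type and 86.0 ± 49.1 FPKM in the labelled group. As Sting1 was not clearly lower in that group, no direction here is known to be that of STING loss.

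By camera 4 lists were higher in the livers labelled Sting knockout. These were ribosomal proteins (36 genes, median 0.65, adjusted p = 9.2e-10), red blood cell genes (7 genes, 1.99, adjusted p = 1.45e-07), nuclear oxidative phosphorylation (32 genes, 0.48, adjusted p = 9.09e-05) and lipogenesis (19 genes, 0.44, adjusted p = 0.0157). Another 3 were lower: interferon-stimulated genes (34 genes, −0.35, adjusted p = 0.00376), Kupffer cell genes (17 genes, −0.53, adjusted p = 0.0051) and female-biased genes (5 genes, −0.87, adjusted p = 0.0103). No call held with an estimated correlation (adjusted p = 0.714 with an estimated correlation for each of the 7). No member passed the gene test. Adjusted over the list alone, 5 red blood cell genes were higher, 1 female-biased gene was lower, and 0 genes of the other 5 lists passed. Rps14, of the small ribosomal subunit, was at 188 ± 70.7 and 494 ± 408 FPKM and Fasn, fatty acid synthase, at 40.5 ± 9.24 and 95.7 ± 62.1 FPKM. Ifit2, an interferon-induced gene, was at 10.9 ± 12.8 and 2.84 ± 1.45 FPKM and Adgre1, the macrophage marker F4/80, at 41.4 ± 19.8 and 22.2 ± 6.71 FPKM.

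Most of these Sting list calls rested on single libraries. Replicate 2 labelled Sting knockout lay apart on the second principal component of its table, at −66.6 where the other 8 libraries lay between −5.3 and 35.6. Without it nuclear oxidative phosphorylation (median 0.02, adjusted p = 0.378) and lipogenesis (median 0.20, adjusted p = 0.0698) did not pass. Without wild-type replicate 3, the library with Xist, female-biased genes did not pass (median −0.10, adjusted p = 0.293). Without wild-type replicate 1 the interferon-stimulated set turned higher (median 0.26, adjusted p = 0.018) and Kupffer cell genes did not pass (adjusted p = 0.638). Without replicate 1 labelled Sting knockout the interferon-stimulated set and lipogenesis did not pass (adjusted p = 0.0725 and 0.212), and without replicate 3 Kupffer cell and female-biased genes did not (0.128 and 0.102). Lipogenesis also failed without wild-type replicate 2 (0.0509). Lipogenesis and nuclear oxidative phosphorylation had medians of −0.024 and −0.015 with array weights, against the direction above. Lipogenesis did not pass under quantile normalization (0.162) or at a mean of at least 5 FPKM (0.107). The ribosomal and red blood cell sets passed without each of the 6 libraries in turn.

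Of 11511 genes tested, limma called 0 higher and 0 lower between the libraries labelled Sting knockout and wild type. An unadjusted p under 0.05 was found for 366, where 575.55 would be expected by chance for these genes. Of 14894 genes tested, edgeR on recovered reads called 0, with 662 under an unadjusted p of 0.05, for which the chance value above does not hold. The limma count was 1089 with the replicate number as a block, 149 and 1409 without replicate 2 or 3 labelled Sting knockout, and 869 without wild-type replicate 2. The groups did not overlap at 5.13% of genes, against 10% by chance. Of coding genes whose groups did not overlap, those with the smallest p did not pass (limma adjusted p = 0.761 each). Among them Hba-a2, 5830473C10Rik and Aacs were higher beside the Hbb genes, and C7, Fam214a, Upp2, Cyp17a1 and Il6ra were lower, in the labelled group. Aacs, which activates acetoacetate for lipid synthesis, was at 9.70 ± 1.42 and 24.3 ± 3.28 FPKM, and C7, a complement component, at 1.81 ± 0.12 and 0.477 ± 0.225 FPKM.

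Hepatocyte Nlrp3 deletion was set against wild type under TAA, which asks what the loss of NLRP3 in hepatocytes changes in this model. Hepatocyte genes rose in the deletion livers: Ahsg, fetuin-A, went from 509 ± 49.3 to 2180.1 ± 670.4 FPKM and Scd1, the stearoyl-CoA desaturase, from 102 ± 21.4 to 497 ± 50.3 FPKM (SD, n = 3, edgeR adjusted p = 0.0487 each). The steepest rise was in Rab43, a small GTPase (chromosome 6, 87788853 to 87812098), from 0.203 ± 0.015 to 29.8 ± 11.1 FPKM (edgeR adjusted p = 0.00152, and 0.0614 and 0.0693 without wild-type replicate 2 or 3). Mitochondrially encoded genes fell, with mt-Nd5 from 4764 ± 697 to 1422 ± 378 FPKM. The calls of Ahsg, Scd1 and mt-Nd5 ended without any 1 library other than deletion replicate 1. For Scd1 the adjusted p was 0.196 and 0.0965 without deletion replicate 2 or 3, and 0.191, 0.177 and 0.196 without wild-type replicate 1, 2 or 3. Gsdmd was at 14.0 ± 3.47 and 11.1 ± 3.5 FPKM and Casp1 at 1.42 ± 0.51 and 1.37 ± 0.23 FPKM, and neither passed (edgeR adjusted p = 0.154 and 0.438). Il18 did not pass either (edgeR adjusted p = 0.813), and its scales differ in sign, with a mean of 4.83 and 5.68 FPKM and an edgeR log2 fold change of −0.13. Over the 11060 genes tested on both scales the median fold change was 0.33 on log2(FPKM + 1) and 0.084 by edgeR.

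The libraries of the 2 TAA groups differed in composition. Mitochondrial genes took 27.8 to 34.7% of counts in wild type and 5.63 to 12.5% in the deletion group. The rRNA genes took 1.17 to 9.14% and 0.267 to 0.386%, and Alb, albumin, 1.42 to 1.62% and 4.37 to 6.61%. Of 846 olfactory and vomeronasal receptor genes, which liver is not known to use, 326 to 474 had a count in the wild-type libraries and 38 to 191 in the deletion libraries. Deletion replicate 1 lay closest to wild type on each of these measures except rRNA.

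**Figure D3:**
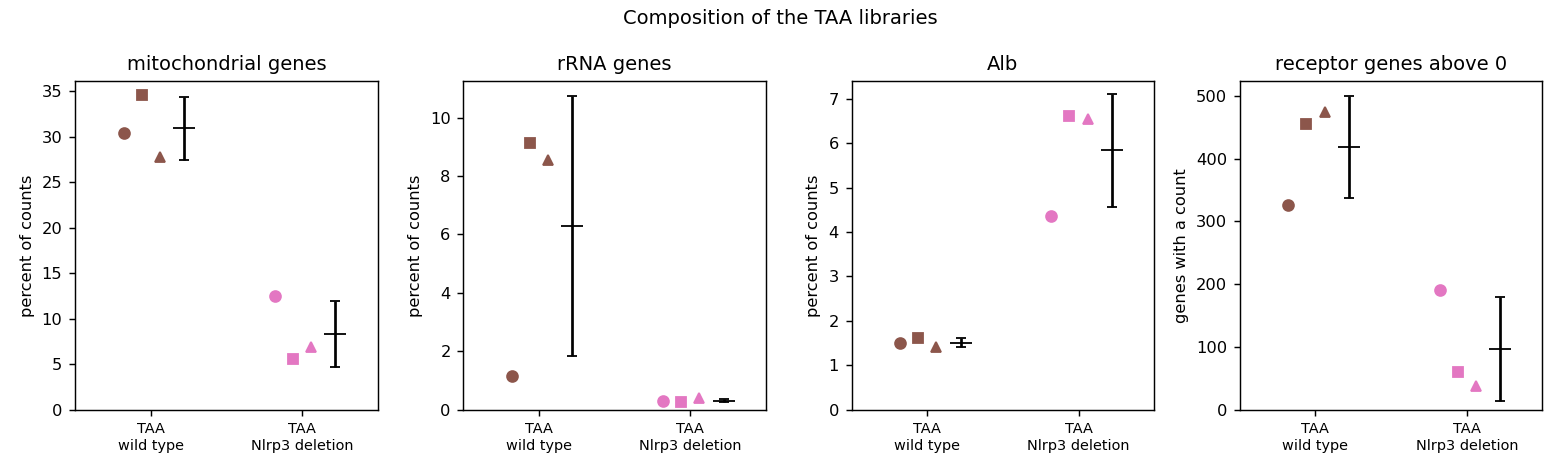
Percent of counts on mitochondrial genes, on rRNA genes and on Alb, and the number of receptor genes with a count, per TAA library (1 point each, 3 per group), with the group mean and SD as a black dash and bar. Mitochondrial genes take 27.8 to 34.7% of counts in wild type and 5.63 to 12.5% in the deletion group.

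By camera 16 lists were higher and 2 lower in the Nlrp3 deletion livers, beside that difference in composition, and no call held with an estimated correlation. Hepatocyte identity genes rose in 6 of 24 (15 adjusted over the list alone, camera adjusted p = 3.49e-08, and adjusted p = 0.251 with an estimated correlation). Acute phase proteins rose in 6 of 24 (13 adjusted over the list alone, adjusted p = 3.44e-07, and adjusted p = 0.144 with an estimated correlation), with Serpina3n from 19.2 ± 1.55 to 114 ± 49.1 FPKM. Lipogenesis genes rose in 7 of 19 (11 adjusted over the list alone, adjusted p = 5.98e-08, and adjusted p = 0.221 with an estimated correlation). Fads1, a fatty acid desaturase, went from 12.1 ± 2.33 to 40.9 ± 4.38 FPKM. Cholesterol synthesis genes rose in 3 of 22 (13 adjusted over the list alone, adjusted p = 1.1e-05, and adjusted p = 0.443 with an estimated correlation). Drug-metabolising enzymes rose in 4 of 30 (17 higher and 1 lower adjusted over the list alone, adjusted p = 8.63e-07, and adjusted p = 0.344 with an estimated correlation), with Cyp2c29 from 6.28 ± 2.01 to 55.1 ± 32.4 FPKM. Periportal genes rose in 2 of 18 (9 adjusted over the list alone, adjusted p = 1.01e-05, and adjusted p = 0.432 with an estimated correlation), with Aldh1b1 from 11.2 ± 2.64 to 83.5 ± 41.8 FPKM.

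Nuclear oxidative phosphorylation genes rose in 2 of 33 in the Nlrp3 deletion livers (18 adjusted over the list alone, camera adjusted p = 7.28e-07, and adjusted p = 0.221 with an estimated correlation), with Cox5a from 18.4 ± 6.64 to 58.7 ± 6.17 FPKM. In contrast 4 of 13 mitochondrially encoded genes fell (13 adjusted over the list alone, adjusted p = 1.12e-16, and adjusted p = 0.304 with an estimated correlation). Fatty acid oxidation genes rose as a set with 0 of 25 past the gene test (15 adjusted over the list alone, adjusted p = 5.79e-07, and adjusted p = 0.344 with an estimated correlation). Ribosomal proteins rose as a set with 0 of 36 (10 adjusted over the list alone, adjusted p = 0.00667, and adjusted p = 0.647 with an estimated correlation). Of NRF2 targets 1 of 22 rose, Gsta4 (7 higher and 1 lower adjusted over the list alone, adjusted p = 0.00949, and adjusted p = 0.639 with an estimated correlation). Immediate early genes fell as a set with 1 of 17, Junb, past the gene test (6 lower and 1 higher adjusted over the list alone, adjusted p = 0.00255, and adjusted p = 0.304 with an estimated correlation). Without deletion replicate 1 the ribosomal and immediate early sets did not pass (0.17 and 0.0573).

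Some lists of other liver cells were also higher as sets in the Nlrp3 deletion livers. Of 20 stellate cell and myofibroblast genes 1 rose, Cxcl12 (7.85 ± 1.21 to 30.1 ± 9.43 FPKM), and 4 did adjusted over the list alone (camera adjusted p = 0.00609, and adjusted p = 0.635 with an estimated correlation). Kupffer cell, recruited macrophage, MHC class II, fibrillar matrix and red blood cell genes passed with 0 members past the gene test (5, 0, 4, 0 and 4 adjusted over the list alone). Their adjusted p were 0.0037, 0.03, 0.0426, 0.03 and 0.0269 (adjusted p = 0.647, 0.669, 0.635, 0.669 and 0.635 with an estimated correlation). Without deletion replicate 3 the macrophage, MHC class II, matrix and red blood cell sets did not pass (0.139, 0.0643, 0.245 and 0.0681), nor red blood cells without deletion replicate 1 (0.0927). Without wild-type replicate 1 the macrophage, MHC class II and matrix sets did not pass (0.0747, 0.108 and 0.0614), nor macrophages without wild-type replicate 2 (0.0554). These 6 sets and NRF2 targets also failed with limma on FPKM. Sinusoidal endothelium, cholangiocyte, neutrophil, T and NK cell, and B and plasma cell genes did not pass (adjusted p = 0.0672, 0.638, 0.493, 0.625 and 0.696). The inflammasome, cGAS-STING, interferon-stimulated and NF-kB lists did not pass either (adjusted p = 0.73, 0.384, 0.131 and 0.109).

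Of 18619 genes tested, edgeR called 255 higher and 67 lower in the Nlrp3 deletion livers. An unadjusted p under 0.05 was found for 5375, and the groups did not overlap at 34.5% of genes, against 10% by chance. Other steep rises were in Ugt1a6b, C1qtnf5, Ugt3a2, Nubpl, Gm5096, Gm4951 and Mrpl53. Ugt1a6b shares exons with its Ugt1a neighbours, so its value is uncertain. The steepest falls were in the predicted genes Gm10719, Gm10720, Gm10721 and Gm10722 near the start of chromosome 9 (3000922 to 3020891) and Gm10801 on chromosome 2, followed by Lars2, Car15 and mt-Co1. Gm10719 had 178 to 671 reads per wild-type library, 1144 in all, and 0 over the deletion group. Lars2, the mitochondrial leucyl-tRNA synthetase, went from 624 ± 428 to 18.2 ± 5.67 FPKM. The groups also differed in their share of rRNA and receptor gene counts. Whether the falls in Lars2 and the predicted genes come from rRNA or genomic DNA reads was not tested.

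The count of Nlrp3 deletion calls lies close to its threshold and rests on single libraries. A threshold of 0.04 left 1 gene higher and 0 lower and one of 0.06 gave 878 and 361. Without deletion replicate 1 edgeR called 3570 higher and 3985 lower. Without deletion replicate 2 or 3 it called 1 and 2 higher and 1 and 1 lower, without wild-type replicate 1 it called 6 and 10, and without wild-type replicate 2 or 3 it called 0 (4188 and 3902 at an unadjusted p under 0.05). DESeq2 called 2035 and 1738, RLE size factors gave 1 and 0, and limma on log2(FPKM + 1) gave 2426 and 216. The share of calls that were higher was 91.8% by limma and 79.2% by edgeR.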

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

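Settings chosen after seeing the data were edgeR on recovered reads, the fit without mitochondrial, rRNA and pseudogene counts, the thresholds of 0.04 and 0.06 and the CCl4 fit without replicate 2 labelled Sting knockout. The others were planned. For values that moved, the cause was not tested, except that fewer libraries or genes enter a fit that leaves them out. The pseudocount, quantile, trend, array weight and TMM-like settings act on FPKM and were not run for the TAA counts. Depth limits the low genes, as Nlrp3 had 0 to 4 recovered reads per hepatocyte library.

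For MCC950, no filter gave 1 gene higher and 1 lower, and leaving out 1 library 0 to 1 lower. The replicate block gave 0 and 0, but its numbers did not pair the libraries by the rule (correlations 0.18, 0.22 and 0.085). Of 3 lists past camera, an estimated correlation and fry kept 0, while TMM-like scaling gave 1, no filter 5, edgeR on recovered reads 5 and leaving out 1 library 1 to 4. For CCl4 the count of genes higher was 363 at a mean of at least 5 FPKM, 1813 with array weights, 1969 with edgeR on recovered reads and 674 to 1274 with 1 library left out. The count lower was 1967 with array weights and 262 to 1198 with 1 library left out, the last of these without replicate 2 labelled Sting knockout. An estimated correlation kept 1 of 32 lists. Of 90 called named genes, 65 stayed called in each setting and 25 lost the call in some, and 0 reversed.

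For Sting, no filter gave 2 genes lower, and leaving out 1 library 0 to 1. Of 7 lists, an estimated correlation and fry kept 0, while no filter gave 12, quantile normalization 16, the 2 groups alone 11, edgeR on recovered reads 17 and leaving out 1 library 7 to 20. With array weights the medians of lipogenesis and nuclear oxidative phosphorylation were −0.024 and −0.015 for Sting. For the Nlrp3 deletion (255 higher, 67 lower) the counts were 1 and 0 with RLE size factors, 1137 and 456 with no filter, 472 and 384 at a mean of at least 5 FPKM, 408 and 120 with robust moderation, and 640 and 199 for coding genes. They were 2035 and 1738 with DESeq2, 2426 and 216 with limma, 560 and 137 without mitochondrial, rRNA and pseudogene counts, 1 and 0 at 0.04 and 878 and 361 at 0.06. Leaving out 1 library gave 0 to 3570 and 0 to 3985. The replicate block gave 2 and 0, but the numbers did not pair these libraries (correlations 0.075, −0.036 and −0.024). Of 18 lists, an estimated correlation kept 0, and fry gave 8, a mean of at least 5 FPKM 10 and limma 11. Of 40 called named genes, 0 stayed called in each setting.

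Reversals were in genes that were not called. With 1 library left out, log2 fold changes ranged for MCC950 in Il18 from −0.0081 to 0.12, and for CCl4 in Gsdmd from −0.15 to 0.37 and in Il18 from −0.014 to 0.45. For Sting they ranged in Pycard from −0.11 to 0.089, in Casp4 from −0.35 to 0.042, in Gsdmd from −0.12 to 0.40, in Il1b from −0.53 to 0.070 and in Il18 from −0.78 to 0.025. For Sting, TMM-like scaling gave −0.034 in Pycard, and array weights gave 0.099 in Casp4, −0.043 in Gsdmd and 0.058 in Il1b. For the Nlrp3 deletion they ranged in Nlrp3 from −0.15 to 0.66, in Il1b from −0.16 to 1.20 and in Il18 from −0.44 to 0.048, and limma gave 0.18 in Il18. The correlation of Sting and Nlrp3 fold changes over genes was 0.027, and −0.051 at a mean of at least 5 FPKM.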

Other observations

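Chosen only after results were seen were the contrast of the libraries labelled Sting knockout with oil, the overlaps by gene name, and the tests of poly(A) selection, of rRNA removal, of hepatocyte share, of a mislabelled sample and of a female mouse. Against oil, many genes changed in the livers labelled Sting knockout. Col1a1 went from 1.10 ± 0.38 to 86.0 ± 49.1 FPKM, Gpnmb from 0.0516 ± 0.0054 to 16.3 ± 6.44 FPKM and Acta2 from 1.33 ± 0.53 to 76.8 ± 20.8 FPKM, while Glul went from 266 ± 21.7 to 19.2 ± 2.36 FPKM and Cyp2e1 from 3236 ± 847 to 186 ± 170 FPKM (SD, n = 3; limma adjusted p = 0.00011, 2.38e-05, 0.000757, 3.6e-05 and 0.00313). Cell cycle genes rose in 30 of 31, matrix genes in 19 of 26 and recruited macrophage genes in 18 of 20, and pericentral genes fell in 9 of 16. Other lists passed in only one of the 2 contrasts, whose difference is the Sting comparison of the report. Of the lists named next, ribosomal protein, red blood cell, nuclear oxidative phosphorylation and female-biased genes passed there (adjusted p = 9.2e-10, 1.45e-07, 9.09e-05 and 0.0103, and adjusted p = 0.714 with an estimated correlation for each), and the others did not. Ribosomal protein, red blood cell, and mesothelium and muscle genes passed camera as higher (adjusted p = 1.88e-05, 0.0102 and 0.0433, and adjusted p = 0.549, 0.444 and 0.549 with an estimated correlation). The cGAS-STING, T and NK cell, cholangiocyte, cholesterol synthesis, nuclear oxidative phosphorylation and female-biased lists, which passed in wild type, did not (adjusted p = 0.209, 0.0568, 0.274, 0.214, 0.0708 and 0.0886). The MHC class II set passed camera in both contrasts (in the labelled group median 1.06, adjusted p = 0.00434, and adjusted p = 0.444 with an estimated correlation). There 1 of 7 members passed the gene test, against 5 of 7 in wild type. limma called 921 genes higher and 680 lower, of which 772 and 477 were called the same way in wild type, against 84.7 and 41.8 for independent lists; 0 were called the opposite way. The contrasts share the oil libraries, and unchanged groups simulated against them shared 0.64 calls on average and 32 at most. These simulated groups held no CCl4 change, so few genes could be called in either contrast. Their shared calls are therefore no measure of the overlap expected between the called lists. Over all genes the fold changes of the contrasts had r = 0.884, inside the central 95% of the simulated groups (−0.496 to 0.894). How much of the overlap comes from the 3 shared libraries was not measured, as they are too few to split.

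Between models, 51 genes were lower under CCl4 and higher in the Nlrp3 deletion livers under TAA, against 14.7 for independent lists, and 2 were higher in both, against 22.1. At a mean of at least 5 FPKM these were 46 against 20.3, a smaller excess, and 0 against 7.67. These overlaps rest on the 255 higher calls of the Nlrp3 deletion, which were 0 to 6 without any 1 library other than deletion replicate 1, and 1 with RLE size factors. Among the 51, named here after their values were seen, were Gnmt, a glycine methyltransferase (log2 fold changes −2.24 and 2.19), the bile acid transporter Slc10a1 (−1.85 and 2.49), Cyp2c29 (−1.90 and 2.76) and Cyp8b1 (−3.82 and 1.32). Over all genes the fold changes had r = −0.12, and 50 of 100 pairings of regrouped libraries gave one as large. Of genes called under CCl4, 66.9% had the opposite sign between the libraries labelled Sting knockout and wild type. Simulated unchanged groups sharing the wild-type libraries gave 65.1% (central 95% of draws 32.9 to 87.2%). The covariance was −0.228, just outside the central 95% of simulated values (−0.225 to 0.0386, mean −0.0505). Across the 11511 tested genes 60.7% were opposite, with a covariance of −0.0867, inside the simulated −0.226 to 0.046. The simulated groups held no CCl4 change, unlike the called genes, and calling was not redone in each draw. The simulation therefore does not give the share expected for called genes without a knockout difference, and no conclusion is drawn. H19, an imprinted RNA of fetal liver, also named after its values were seen, had 128, 91 and 157 counts in wild type and 2688, 11153 and 689 in the deletion livers (edgeR adjusted p = 0.0519, not passing).

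The 322 calls between the TAA groups compare with at most 1 in the other 9 of 10 splits, too few splits for a share under 0.05. A difference in poly(A) selection stays undecided. The messages of replication-dependent histone genes lack a poly(A) tail, and 28 of these genes had a median log2 fold change of 0.25 (SE 0.21) beside 0.05 for cell cycle genes. This lay within the bound for arguing against the explanation, but the bound was written after results were seen. A first set of 4 genes under older symbols gave −0.71 (SE 0.61) and was replaced after this was seen. The SE are over genes and leave out the spread between libraries. Reads of genes on opposite strands, as a cause of the calls as a whole, are argued against by a share of overlapping genes among called over tested of 0.93. This share pools all calls and any overlap of exons, so it leaves single genes open. The explanation of a few genes taking most of the counts stays undecided. Without mitochondrial, rRNA and pseudogene counts 697 were called, 285 of them shared with the 322, a rise where it predicts a fall. This lies outside the 1.5 times set in advance for arguing against it, and the count depends steeply on its threshold. A lower hepatocyte share in wild type stays undecided too. Stellate, Kupffer, endothelial and cholangiocyte medians were 0.52, 0.87, 0.59 and 0.05 (SE 0.15, 0.26, 0.22 and 0.18), beside 0.96 for hepatocyte identity. These SE are over genes that move together and leave out the spread between libraries. A difference in rRNA removal (lowest rRNA share in wild type 3.03 times the highest in the deletion group) and genomic DNA in the wild-type libraries stay open and may contribute: receptor genes took 106 to 158 CPM in wild type and 22.6 to 63.2 CPM in the deletion group, a ratio of 1.67 between the nearest libraries, between the bounds set in advance. RNA quality and the deletion itself are confounded with the groups, and no biological explanation was tested.

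No genes were called between the libraries labelled Sting knockout and wild type. With 0 calls observed, each of 10 splits gives at least as many whatever the data (highest other 1), so the splits test nothing here. Of the 4 splits that part every pair, the others gave 0. A mislabelled sample cannot be told apart from an allele that leaves the RNA: the highest Sting1 in that group was 5.28 FPKM, inside the wild-type range. The codes in the titles of all 3 libraries begin with SWT, and the sources used here do not say what this stands for. Too few replicates for the spread stays open, as 60% of simulated 4-fold changes were recovered. For MCC950, 0 calls were observed too, so each of 10 splits gives at least as many whatever the data (highest other 1), and nothing is tested.

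Male-biased transcripts were lower under CCl4, in a comparison where the real split gave 1766 calls, as many in 1 of 10 splits, and the others 0, too few for a share under 0.05, also among the 4 that part every pair. They fell further than hepatocyte identity genes in these libraries, with medians differing by −2.37 (SE 0.54). Without the library that holds Xist the difference was −1.93 (SE 0.48). These SE are over list genes, which move together (estimated correlation 0.70 and 0.38), and leave out the spread between libraries. The values therefore do not decide on fewer hepatocytes. In wild type without the library that holds Xist the male-biased median was still −2.63. The CCl4 libraries labelled Sting knockout held Xist at most at 0.0129 FPKM and Ddx3y at least at 8.76 FPKM. Against the same oil libraries their male-biased median was −2.96, with 9 of 14 genes lower (camera adjusted p = 5.7e-09, and adjusted p = 0.292 with an estimated correlation). These values argue against the female mouse as the whole cause of the fall. Reads shared between Mup copies are argued against by a median of −3.28 over the 13 members that are not Mup genes. The list holds 1 Mup gene, so this leaves the falls of the Mup genes themselves open. Whether oil and CCl4 mice differ in sex was undecided by the test set in advance, as the lowest Y-linked value was 0 FPKM, in that 1 library alone. A change of the male pattern of hepatic expression with CCl4 stays a hypothesis beside the explanations left open, found and tested on the same data.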
